A study of Mus musculus with 6 samples.

How the data were processed

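The series holds 6 samples of mouse cells, each measured on 1 Mouse Gene 2.0 ST array, an array of short oligonucleotide probes combined into probe sets. Per the labels' protocols, inflammatory monocytes (CD11b-positive, CD11c-negative, Ly6C-high) were sorted by flow cytometry 10 days after the transfer of Th9 cells, from spleen (3 samples) and from tumor (3 samples), and RNA with an integrity number above 8.50 was labelled with biotin. The kind of tumor and the strain of mouse are not given in the sources used here. The authors deposited 1 table with 1 intensity per probe set and array, on a linear scale. Per the submitters' processing notes it was made with RMA, a method of background correction, normalization and summary over probes, for which no version or setting is given. The values do not lie on 1 common distribution, since array medians of log2 intensity were 4.51, 4.50 and 4.73 for spleen 1 to 3 and 4.51, 4.51 and 4.76 for tumor 1 to 3, and the 95th percentiles of intensity were 619, 632, 790.2, 683, 649.9 and 827. Whether the step that brings arrays to 1 distribution was left out, or run in separate batches, stays unknown. The genome build behind the array design is not given in the sources used here, so no coordinates are printed.

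Genes were named from the platform's annotation as GEO gives it. Of 41345 probe sets, 23521 carry 1 gene symbol, 1814 carry several and 16010 are not listed with a gene, and only the first kind was used in the gene comparison. Of these, 23328 have a gene identifier found in a RefSeq gene table of the assembly GRCm38.p6, each with the same symbol. They cover 22180 genes, and where a gene has several probe sets (1038 of the genes tested) the one with the highest mean over all 6 arrays stood for it. A gene was tested if its intensity lay above the 25th percentile of its array on at least 3 arrays, which left 18458 genes. Values were used as log2(intensity + 1), because the table turned out to be linear where log2 values had been foreseen, and folds are on that scale, which understates changes of dim genes. Probe sets of closely related genes can read each other's transcripts, which applies to the families Ifit, Oas, Gbp, Ms4a, Slfn and Ifna.

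Tumor was compared with spleen by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with group as the only term and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05, and the count at 2-fold or more is given too. An exact test of 3 against 3 arrays cannot give a p below 0.1. Before the data were examined 38 gene lists were fixed, 22 of functions and 16 of markers of other cell types, and each was tested with camera (preset inter-gene correlation 0.01, adjusted over the 38 lists), with camera using an estimated correlation, and with fry, which asks whether the members move, on balance, 1 way and does not set them against other genes. None of the camera calls held with an estimated correlation. Also fixed then was the rule for named genes: the genes behind the sort (Itgam, Itgax, Ly6c1, Ly6c2, Ccr2 and Adgre1), the 12 largest called rises and the 12 largest called falls with groups that do not overlap, leaving out predicted genes, small RNAs and receptor segments, up to 3 called members per direction of each functional list, or the 2 of smallest p where none was called, and from each marker list the 2 largest changes and the 2 highest levels. A further 2 lists, of genes high in bone marrow cells cultured with GM-CSF and of genes of Ly6C-high monocytes, were written after the levels of some of their members had been seen, as were the gene families grouped by symbol.

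Equal replicate numbers were checked for pairing. Deviations from the group means correlated at 0.36, 0.44 and 0.71 across genes between the spleen and tumor arrays numbered 1, 2 and 3. Spleen 1 with tumor 2 (0.46) and spleen 2 with tumor 1 (0.35) correlated as well. Deviations from a group mean cancel out, so a deviation shared by the arrays numbered 3 makes the others correlate too. The values therefore set number 3 apart in both groups, and do not show that equal numbers pair among numbers 1 and 2. The labels do not say what a shared number means, and genes are not independent replicates. The first principal component, with 59.5% of the variance, parted tumor from spleen, and the second, with 31.6%, parted number 3 from numbers 1 and 2 in both groups. Values with the replicate number as a block, and within the arrays numbered 1 and 2 and the pair numbered 3, are therefore given where they bear on a result.

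Alternatives fixed beforehand were quantile normalization, median centring and cyclic loess of the deposited values, no filter and a 50th percentile filter, the mean of a gene's probe sets, a trended and robust prior, an unmoderated fit, array weights, the replicate block, an adjusted p under 0.01, limma's treat at 1.5-fold, the other set tests, and each array left out in turn. Chosen after seeing the data were no pseudocount, both arrays numbered 3 left out, number 3 as a batch term, and quantile normalization with the replicate block. The fit was tested on simulated arrays with the real means and spreads and 50 genes changed by each of 4 sizes, where limma called 0 at a log2 change of 0.5, 22 at 1, 48 at 2 and 48 at 3, with 8 false calls among 18458 genes, 6.35% of all calls. With the replicate block the calls were 0, 0, 37 and 45. The simulated arrays lacked the deviation shared by the real arrays with equal numbers, so the blocked fit was not tested on such arrays. In the same kind of test 1 list shifted by a log2 change of 1 was called and 0 of the others were. Simulated genes were drawn independently of each other. That test therefore does not show how often camera calls a list falsely where members vary together, as in the real lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.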

Results

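RNA of 6 samples of flow-sorted mouse cells was measured on Mouse Gene 2.0 ST arrays, which carry many short probes per gene and give 1 intensity per probe set. All mice had received Th9 cells, a type of helper T cell, 10 days before tissue was taken. The cells were sorted as inflammatory monocytes, positive for CD11b, negative for CD11c and high for Ly6C, from spleen (n = 3 arrays) or from tumor (n = 3 arrays). The comparison asks how such cells differ between the tumor and the spleen of treated mice. Array medians of log2 intensity lay between 4.50 and 4.51 on the arrays numbered 1 and 2 of both groups, and at 4.73 and 4.76 on those numbered 3. The number of arrays limits the precision. Nothing in the labels says whether the 3 samples of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical. Levels are log2(intensity + 1), given as mean ± SD (n = 3), and changes are tumor minus spleen on the same scale, given ± SE. Where a gene is said to stand at a value, that value is its difference, tumor minus spleen.

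The genes behind the sort were read first. Itgam, which encodes CD11b, had a level of 10.04 ± 0.15 in spleen and 9.19 ± 0.22 in tumor, a fall of 0.85 ± 0.17 (limma adjusted p = 0.015). Itgax, which encodes CD11c, the marker the sort selected against, had a level of 11.16 ± 0.12 in spleen and 10.31 ± 0.17 in tumor (adjusted p = 0.00986). Ly6c2, 1 of the genes behind Ly6C staining, rose from 6.81 ± 0.58 to 8.29 ± 0.40 (adjusted p = 0.0185), while Ly6c1 lay near the floor in both groups, at 3.65 ± 0.68 and 4.01 ± 0.40 (adjusted p = 0.693). Ccr2, the chemokine receptor of classical monocytes, fell from 6.86 ± 0.09 to 5.93 ± 0.15 (adjusted p = 0.00515). Adgre1, which encodes F4/80, stood at -0.57 ± 0.20 (adjusted p = 0.121, and adjusted p = 0.00257 with the replicate block). Itgam without spleen 2 or tumor 1/2 (adjusted p up to 0.0801), Itgax without tumor 1 (adjusted p = 0.0594) and Ly6c2 without spleen 1/2 (adjusted p up to 0.0711) lost the call. Groups are named after their labels, as tumor arrays and spleen arrays.

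**Figure D1:**
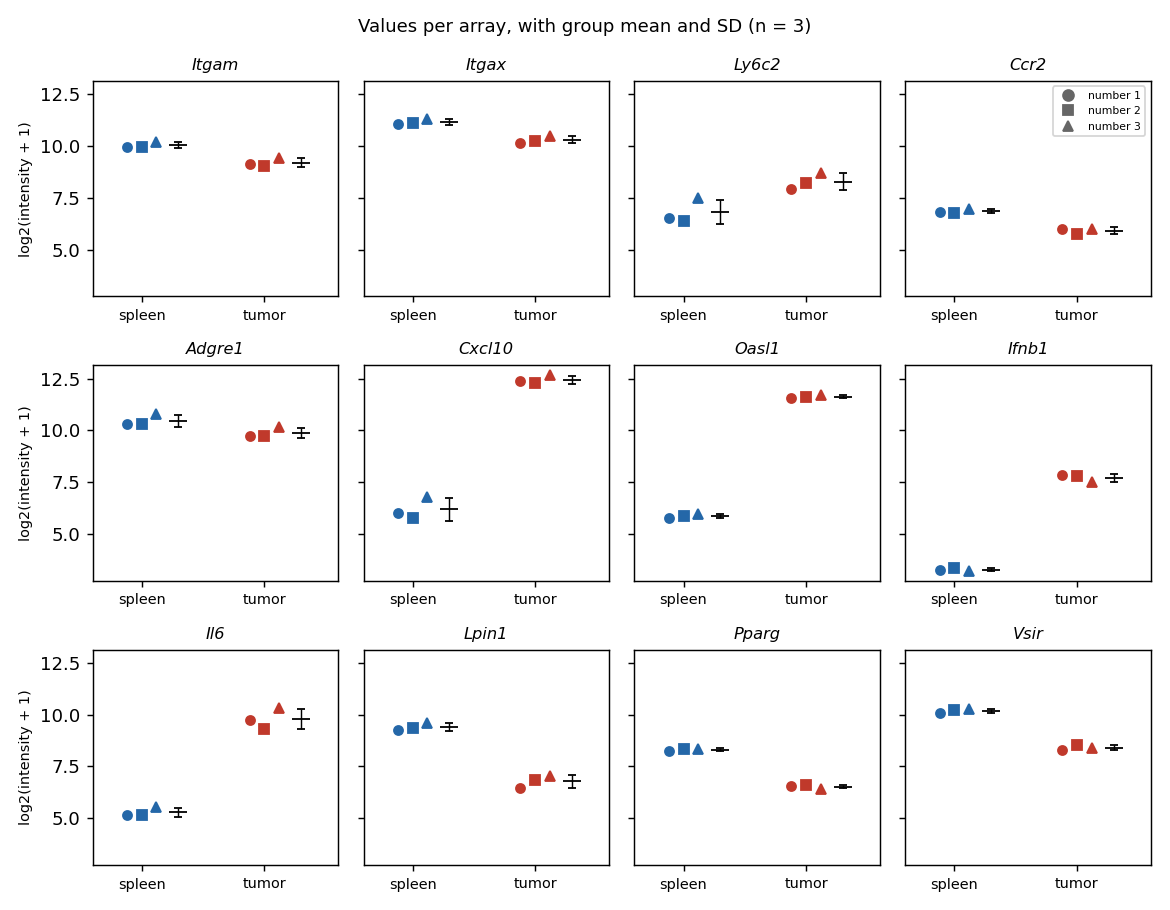
Level of 12 named genes on each array, as log2(intensity + 1), with the mean and SD of each group (n = 3) in black and the replicate number as the marker shape. Itgax lay between 10.16 and 11.30 on all 6 arrays, and Cxcl10, Oasl1, Ifnb1 and Il6 were higher on all 3 tumor arrays than on any spleen array.

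Genes induced by interferon led the rises on the tumor arrays, and the falls were smaller and more mixed. The largest called rise, leaving out predicted genes, was that of Cxcl10, a chemokine that draws activated T cells, by 6.24 ± 0.27 (75.8-fold, adjusted p = 3.7e-06; probe set 17449718, Entrez gene 15945). The antiviral genes Ifit1bl1 (6.22 ± 0.43), Oasl1 (5.75 ± 0.14), Mx2 (5.39 ± 0.14) and Ifit1 (5.26 ± 0.18) rose with it. So did the GTPase Iigp1 (5.96 ± 0.27), the DNA-sensor family members Ifi205 (5.96 ± 0.17), Ifi213 (5.28 ± 0.32) and Ifi208 (5.23 ± 0.26), Trim30c (5.53 ± 0.17), the activation antigen Cd69 (5.57 ± 0.15) and Tnfsf10, the death ligand TRAIL (5.29 ± 0.22). Iigp1 (3.88), Ifi213 (3.46), Ifi208 (2.91) and Trim30c (4.40) had spleen levels under the 25th percentile of the tested genes (4.42), where background limits the size and the rank of a difference. Falls were smaller, with Lpin1, a phosphatidic acid phosphatase of lipid synthesis, lowest among the genes the naming rule keeps, at -2.64 ± 0.19 (adjusted p = 6.1e-05, probe set 17280062, Entrez gene 14245). Kcnn3 (-2.60 ± 0.23), the retinal reductase Dhrs3 (-2.53 ± 0.14), the lipase inhibitor Angptl4 (-2.48 ± 0.14) and Herpud1, a gene of protein degradation at the endoplasmic reticulum (-2.39 ± 0.14), followed. The list of 12 went on with B3gnt7 (-2.26 ± 0.15), the iron exporter Slc40a1 (-2.18 ± 0.18), the myeloid transcription factor Cebpa (-2.14 ± 0.15), Mlph (-2.13 ± 0.17), Ypel2 (-2.11 ± 0.32), Cd300lb (-2.07 ± 0.15) and Tmem154 (-2.01 ± 0.20). These 24 genes kept their call with each array left out in turn, and adjusted p lay between 7.8e-07 and 0.00403. B3gnt7 has 2 probe sets, whose changes were -2.26 and -0.10.

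Of 18458 genes tested, 1952 differed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 1057 higher and 895 lower in tumor. At least 2-fold changes numbered 984, with 690 higher and 294 lower. Rises reached further than falls, since 96 called genes rose 8-fold or more and 0 fell as far, called or at an unadjusted p under 0.05, against 224 up and 13 down at 4-fold. In all 1952 called genes the 3 tumor values lay on 1 side of the 3 spleen values, which held for 25.4% of the tested genes and holds for 10% by chance. A call with 3 arrays per group nearly requires such a separation, so it adds no support for the called genes. With the replicate block the count was 5346 (2153 higher, 3193 lower), and among the arrays numbered 1 and 2 alone, a choice made after seeing the data, it was 2936 (958 at least 2-fold). In 74 of the called rises and 15 of the called falls the lower group lay under the 25th percentile of the tested genes, and such genes are called dim. The arrays numbered 3 are 1 pair and have no test of their own. Leaving out spleen 1, spleen 2 or tumor 1 lowered the count to 1147, 1031 and 1011, and leaving out tumor 2 lowered the count of falls to 443.

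**Figure D2:**
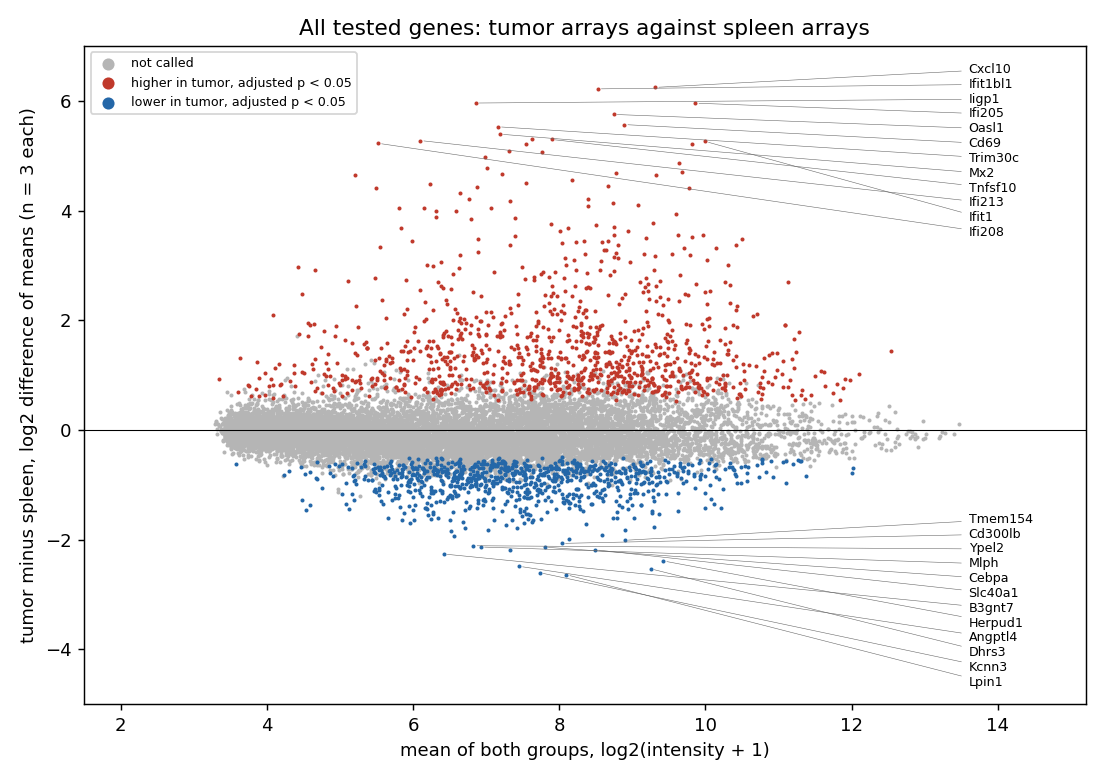
Each dot is 1 of 18458 tested genes, with the mean level of both groups on the horizontal axis, log2(intensity + 1), and the log2 difference tumor minus spleen on the vertical axis (n = 3 each). Red and blue mark the 1057 genes higher and the 895 lower at an adjusted p under 0.05. The 12 largest called changes each way are named, with predicted genes, small RNAs and receptor segments left out.

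Genes induced by type I interferon rose together. All 36 tested members of this list were higher in tumor. The type I interferon counts were the same adjusted over the list alone. Type I interferon differences had a median of 3.22 (3.19 among numbers 1 and 2, 3.09 in number 3), with a camera adjusted p = 4.8e-65, or adjusted p = 0.0644 with an estimated correlation. Interferon-gamma-inducible genes followed, with 18 of 20 higher and 0 lower. The interferon-gamma genes had 18 higher and 1 lower adjusted over the list alone, and 19 higher and 1 lower with the replicate block, with 1 lower at an unadjusted p under 0.05 by limma. Interferon-gamma differences had a median of 3.28 (3.20 among numbers 1 and 2, 3.33 in number 3), with a camera adjusted p = 6.7e-31, or adjusted p = 0.0644 with an estimated correlation. Besides Cxcl10 and Iigp1, the chemokine Cxcl9 led this list at 5.06 ± 0.26 (adjusted p = 8.8e-06). Many of these genes respond to both kinds of interferon. Among the genes that sense nucleic acids and start interferon production, 11 of 19 rose and 1 fell. Irf7, Zbp1, Ddx58 and Ifih1 also belong to the type I interferon list, so their rises are counted in both lists. The nucleic acid sensing genes had 13 higher and 1 lower adjusted over the list alone. Nucleic acid sensing differences had a median of 1.59 (1.55 among numbers 1 and 2, 1.49 in number 3), with a camera adjusted p = 5.7e-14, or adjusted p = 0.317 with an estimated correlation. Its largest rises were those of Irf7, the transcription factor that amplifies interferon production (4.42 ± 0.16, adjusted p = 2.2e-06), of Ifnb1, the interferon beta gene itself, dim in spleen (4.41 ± 0.15, from 3.29 ± 0.06 to 7.71 ± 0.19), and of Zbp1 (3.77 ± 0.18). Mavs, the adaptor of the RNA sensors, fell by 0.95 ± 0.17 (adjusted p = 0.01). Mavs without tumor 1 (adjusted p = 0.0564) lost the call.

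Inflammatory cytokine genes and other NF-kB targets rose with them, 17 of 23 higher and 0 lower. The NF-kB genes had 21 higher and 0 lower adjusted over the list alone, with 0 lower at an unadjusted p under 0.05 by limma. NF-kB differences had a median of 1.40 (1.46 among numbers 1 and 2, 1.26 in number 3), with a camera adjusted p = 4.3e-25, or adjusted p = 0.317 with an estimated correlation. Il6 led at 4.50 ± 0.25 (adjusted p = 1.5e-05), followed by Ptgs2, the inducible cyclooxygenase (3.56 ± 0.18), and Il15, a growth factor of NK and memory T cells (3.45 ± 0.23). Chemokine genes had 11 of 22 members higher and 0 lower. The chemokine counts were the same adjusted over the list alone, and 12 higher and 1 lower with the replicate block, with 0 lower at an unadjusted p under 0.05 by limma. Chemokine differences had a median of 0.59 (0.49 among numbers 1 and 2, 0.79 in number 3), with a camera adjusted p = 5.1e-09, or adjusted p = 0.317 with an estimated correlation. Within this list Ccl4 came after Cxcl10 and Cxcl9, at 3.75 ± 0.23 (adjusted p = 2.5e-05). Cxcl11, a chemokine outside the list that was chosen after its value was seen, rose by 5.21 ± 0.23 (adjusted p = 4.7e-06). Chemokine receptors and trafficking molecules went both ways, with 3 higher and 4 lower of 19 and no call for the list. The trafficking counts were the same adjusted over the list alone, and 5 higher and 6 lower with the replicate block. Trafficking differences had a median of -0.13 (-0.16 among numbers 1 and 2, -0.06 in number 3), with a camera adjusted p = 0.866. Ccrl2 (2.52 ± 0.16, adjusted p = 3.3e-05), Ccr1 (0.80 ± 0.16) and Ccr7 (0.54 ± 0.14) were higher. The integrin subunit Itgb7 (-0.98 ± 0.20), the transcription factor Klf2 (-0.95 ± 0.18) and Ccr2 (-0.93 ± 0.15) were lower, as was Cxcr4 (-0.59 ± 0.14), chosen after its value was seen. Among numbers 1 and 2 alone Itgb7 and Klf2 were not called (adjusted p = 0.114 and 0.0559). Ccr1 without spleen 1/2 or tumor 1 (adjusted p up to 0.0741), Ccr7 without any one array (adjusted p up to 0.158) and Itgb7 without spleen 1/2 or tumor 1 (adjusted p up to 0.0656) lost the call. Klf2 without spleen 2 or tumor 1 (adjusted p up to 0.062) lost the call.

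Genes of antigen presentation by MHC class I rose in 9 of 17 cases and fell in 0. The MHC class I genes had 11 higher and 1 lower adjusted over the list alone, and 12 higher and 1 lower with the replicate block, with 1 lower at an unadjusted p under 0.05 by limma. MHC class I differences had a median of 0.69 (0.71 among numbers 1 and 2, 0.66 in number 3), with a camera adjusted p = 4.1e-08, or adjusted p = 0.317 with an estimated correlation. Nlrc5, the transactivator of class I genes, changed by 2.84 ± 0.18 (adjusted p = 3.4e-05), and the immunoproteasome subunits Psmb9 and Psmb10 by 1.53 ± 0.14 and 1.46 ± 0.16. In the MHC class II list 3 of 14 members were higher and 1 lower. The MHC class II genes had 3 higher and 2 lower adjusted over the list alone, and 3 higher and 7 lower with the replicate block. MHC class II differences had a median of -0.27 (-0.29 among numbers 1 and 2, -0.25 in number 3) and a mean of 0.11, with a camera adjusted p = 0.765 directed down, while fry pointed up. The members that rose were the costimulatory genes Cd40 (2.82 ± 0.19), Cd80 (1.53 ± 0.34) and Cd86 (1.30 ± 0.21), which do not present peptide. The peptide loader H2-DMa fell by 0.66 ± 0.15 (adjusted p = 0.0244, and adjusted p = 0.065 among numbers 1 and 2). Checkpoint and costimulatory genes were higher in 11 of 19 cases and lower in 1. The checkpoint genes had 12 higher and 1 lower adjusted over the list alone, and 12 higher and 2 lower with the replicate block. Checkpoint differences had a median of 1.30 (1.39 among numbers 1 and 2, 1.13 in number 3), with a camera adjusted p = 9.7e-09, or adjusted p = 0.628 with an estimated correlation. Tnfsf4, the ligand of OX40, rose by 2.40 ± 0.26 (adjusted p = 5.7e-04), after Tnfsf10 and Cd40. Vsir, which encodes the inhibitory receptor VISTA, fell by 1.77 ± 0.15 (adjusted p = 1.4e-04). Cd80 without spleen 1/2 or tumor 1/3 (adjusted p up to 0.0927) and H2-DMa without spleen 1/2 or tumor 1 (adjusted p up to 0.122) lost the call.

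**Figure D3:**
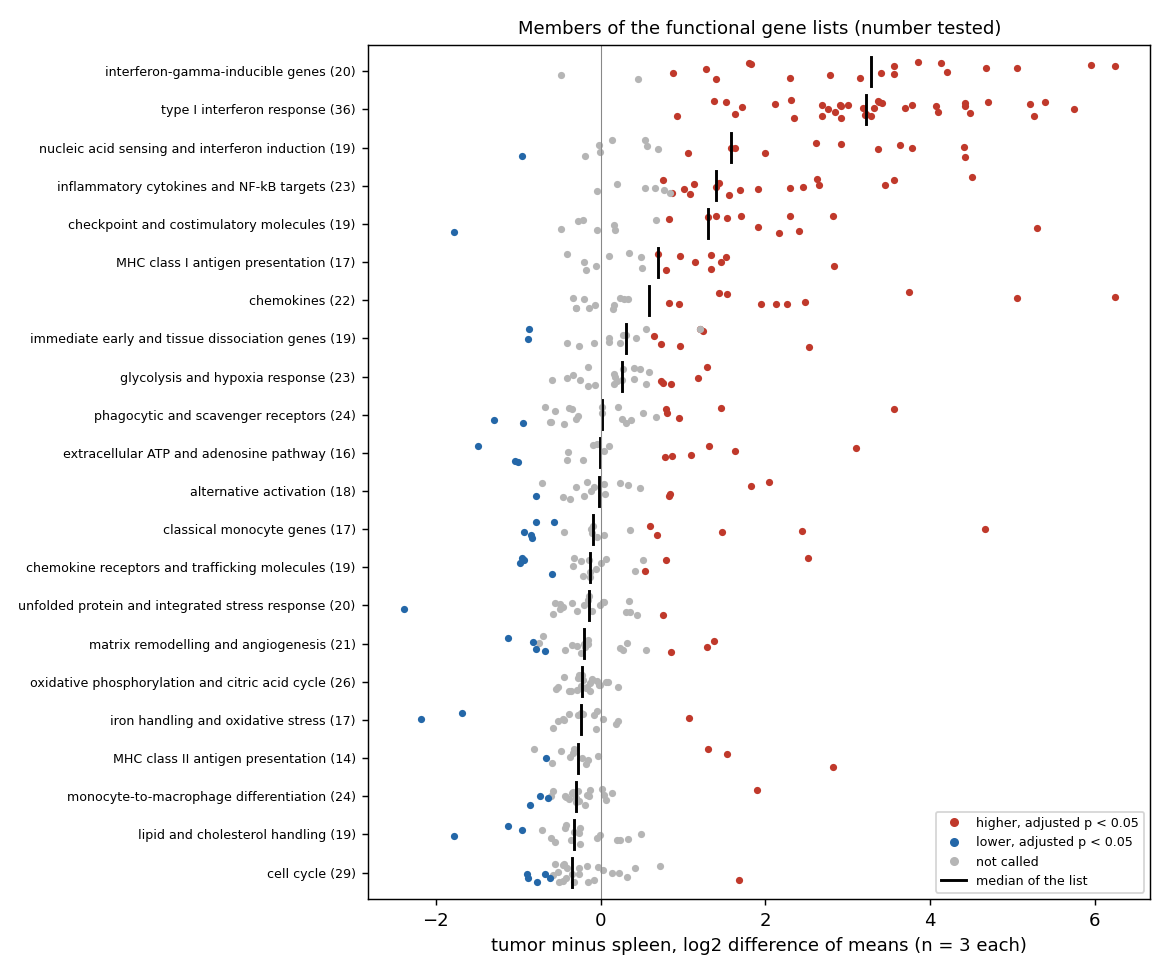
Each dot is a tested member of a functional gene list, placed by its log2 difference tumor minus spleen (n = 3 each), and the bar is the list's median. The interferon lists have medians of 3.22 and 3.28, and no member of the oxidative phosphorylation list was called.

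The genes of the monocyte state itself were split. Classical monocyte genes had 5 members higher and 5 lower of 17, and the list was not called. The classical monocyte counts were the same adjusted over the list alone. Classical monocyte differences had a median of -0.09 (-0.01 among numbers 1 and 2, -0.18 in number 3) and a mean of 0.33, with a camera adjusted p = 0.764 directed up. Ms4a4c (4.67 ± 0.17, adjusted p = 2.2e-06), the matrix proteoglycan Vcan (2.44 ± 0.16) and Ly6c2 rose, while Ccr2, Itgam and the glutathione peroxidase Gpx1 (-0.83 ± 0.18) fell. The other called members, named after their values were seen, were Plac8 (0.68 ± 0.15), Ly86 (0.60 ± 0.15), the receptor gene Csf1r (-0.57 ± 0.15) and Fn1. Genes of monocyte-to-macrophage differentiation had 1 member higher and 3 lower of 24. The macrophage differentiation counts were the same adjusted over the list alone, and 1 higher and 12 lower with the replicate block. Macrophage differentiation differences had a median of -0.30 (-0.29 among numbers 1 and 2, -0.28 in number 3), with a camera adjusted p = 0.0151, or adjusted p = 0.78 with an estimated correlation. The macrophage differentiation call was lost with a 50th percentile filter (adjusted p = 0.0508) and by fry (0.118). Vcam1 rose by 1.90 ± 0.16 (adjusted p = 1.5e-04), and Trem2 (-0.86 ± 0.18) and the complement genes C1qc (-0.74 ± 0.15) and C1qb (-0.64 ± 0.14) fell. The alternative activation list had 4 higher and 1 lower of 18. The alternative activation counts were the same adjusted over the list alone, and 6 higher and 4 lower with the replicate block. Alternative activation differences had a median of -0.02 (-0.09 among numbers 1 and 2, -0.05 in number 3) and a mean of 0.19, with a camera adjusted p = 0.329 directed up. Its called members were Pdcd1lg2, or PD-L2 (0.82 ± 0.15, chosen after its value was seen), the STAT5 target Cish (2.04 ± 0.43), the VEGF receptor Flt1 (1.83 ± 0.22) and Il13ra1 (0.84 ± 0.21) on the higher side, and fibronectin, Fn1 (-0.78 ± 0.16), on the lower side. Phagocytic and scavenger receptors had 5 higher and 2 lower of 24. The phagocytic receptor genes had 7 higher and 6 lower adjusted over the list alone, and 8 higher and 9 lower with the replicate block. Phagocytic receptor differences had a median of 0.01 (-0.00 among numbers 1 and 2, 0.04 in number 3), with a camera adjusted p = 0.487. The rises were led by the Fc receptor Fcgr1 (3.56 ± 0.16, adjusted p = 4.6e-06), Scarf1 (1.46 ± 0.25) and Msr1 (0.95 ± 0.21), with Itgav (0.81 ± 0.15) and Fcgr4 (0.80 ± 0.13) chosen after their values were seen. Itgb5 (-1.29 ± 0.21) and the HDL receptor Scarb1 (-0.95 ± 0.15) fell. The 2 probe sets of Cish stood at 0.62 and 2.04. Among numbers 1 and 2 alone C1qc stood at -0.72 and missed the threshold. Ly6c2 without spleen 1/2 (adjusted p up to 0.0711), Itgam without spleen 2 or tumor 1/2 (adjusted p up to 0.0801) and Gpx1 without spleen 1/2 or tumor 1 (adjusted p up to 0.0966) lost the call. Trem2 without spleen 2 or tumor 1/2 (adjusted p up to 0.0909), C1qc without spleen 1/2 or tumor 2 (adjusted p up to 0.0666) and C1qb without spleen 1/2 or tumor 1 (adjusted p up to 0.132) lost the call. Cish without spleen 1/2 (adjusted p up to 0.0729), Il13ra1 without spleen 1/2 or tumor 1/2/3 (adjusted p up to 0.152) and Fn1 without spleen 2 or tumor 1/2 (adjusted p up to 0.084) lost the call. Msr1 without spleen 1/2 or tumor 1 (adjusted p up to 0.0886) lost the call.

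Receptors of extracellular nucleotides moved apart. Of 16 tested genes of the extracellular ATP and adenosine pathway 6 rose and 3 fell, and the list was not called. The purinergic counts were the same adjusted over the list alone, and 6 higher and 5 lower with the replicate block. Purinergic differences had a median of -0.00 (-0.17 among numbers 1 and 2, 0.23 in number 3) and a mean of 0.27, with a camera adjusted p = 0.267 directed up. P2ry13 (3.10 ± 0.16, adjusted p = 1.0e-05), P2ry14 (1.63 ± 0.16) and P2ry12 (1.32 ± 0.16) were higher. On the other side P2ry6 (-1.48 ± 0.15, adjusted p = 4.2e-04), P2ry2 (-1.04 ± 0.16) and the ATP-gated channel P2rx7 (from 8.18 ± 0.29 to 7.19 ± 0.15) were lower. Genes of glycolysis and the hypoxia response had 5 of 23 members higher and 0 lower. The glycolysis genes had 6 higher and 0 lower adjusted over the list alone, and 10 higher and 2 lower with the replicate block, with 0 lower at an unadjusted p under 0.05 by limma. Glycolysis differences had a median of 0.26 (0.30 among numbers 1 and 2, 0.21 in number 3), with a camera adjusted p = 0.00485, or adjusted p = 0.881 with an estimated correlation. The glycolysis call was lost by fry (adjusted p = 0.225). Vegfa (1.29 ± 0.20, adjusted p = 0.00494), Ndrg1 (1.18 ± 0.15) and Pfkp (0.85 ± 0.21) rose, as did Hilpda (0.76 ± 0.15) and P4ha1 (0.73 ± 0.16), chosen after their values were seen. Ndrg1 was not called on the mean of its 2 probe sets (adjusted p = 0.204). No member of the oxidative phosphorylation and citric acid cycle list passed limma's test, and 3 of 26 were lower at an unadjusted p under 0.05. The oxidative phosphorylation counts were the same adjusted over the list alone, and 0 higher and 5 lower with the replicate block. Oxidative phosphorylation differences had a median of -0.22 (-0.19 among numbers 1 and 2, -0.23 in number 3), with a camera adjusted p = 0.0615. The oxidative phosphorylation list was called after quantile normalization (adjusted p = 0.0287), with no filter on dim probe sets (0.0259), with array weights (0.0293), with the replicate block (0.0382), with number 3 as a batch term (0.0421), with quantile normalization and the block (0.0115), without spleen 3 (0.0493) and without tumor 2 (0.027). Its smallest p belonged to Ogdh (-0.51 ± 0.17, adjusted p = 0.103) and Idh3a (-0.39 ± 0.14, adjusted p = 0.14), both called with the block (adjusted p = 0.00424 and 0.0208). Lipid and cholesterol genes fell in 3 of 19 cases and rose in 0. They were Pparg, a nuclear receptor of lipid uptake (-1.78 ± 0.14, adjusted p = 9.3e-05), fatty acid synthase Fasn (-1.13 ± 0.23) and the carrier Fabp4 (-0.96 ± 0.22). The lipid genes had 1 higher and 8 lower adjusted over the list alone, and 1 higher and 10 lower with the replicate block, with 1 higher at an unadjusted p under 0.05 by limma. Lipid differences had a median of -0.33 (-0.32 among numbers 1 and 2, -0.34 in number 3), with a camera adjusted p = 0.0219, or adjusted p = 0.825 with an estimated correlation. The lipid call was lost with a 50th percentile filter (adjusted p = 0.0723) and by fry (0.0802). Iron handling and oxidative stress genes had 1 higher and 2 lower of 17. The iron genes had 1 higher and 3 lower adjusted over the list alone, and 1 higher and 7 lower with the replicate block. Iron differences had a median of -0.24 (-0.19 among numbers 1 and 2, -0.34 in number 3), with a camera adjusted p = 0.0854. The iron list was called after quantile normalization (adjusted p = 0.0412). The superoxide dismutase Sod2 rose by 1.07 ± 0.27, and the iron exporter Slc40a1 and the transferrin receptor Tfrc (-1.68 ± 0.27) fell. Sod2 missed the threshold among numbers 1 and 2 (adjusted p = 0.051) and with no filter on dim probe sets (adjusted p = 0.0509). P2rx7 without tumor 1 (adjusted p = 0.0594), Pfkp without spleen 1/2 or tumor 1/2/3 (adjusted p up to 0.148) and Fasn without spleen 2 or tumor 1/2 (adjusted p up to 0.0772) lost the call. Fabp4 without spleen 1/2/3 or tumor 1/2 (adjusted p up to 0.103) and Sod2 without spleen 1/2 or tumor 1/3 (adjusted p up to 0.152) lost the call.

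Cell cycle genes had 1 member higher and 5 lower of 29. The cell cycle counts were the same adjusted over the list alone, and 4 higher and 15 lower with the replicate block. Cell cycle differences had a median of -0.34 (-0.32 among numbers 1 and 2, -0.35 in number 3), with a camera adjusted p = 0.0541. The cell cycle list was called after median centring (adjusted p = 0.0489), with no filter on dim probe sets (0.0259), without spleen 1 (0.033) and without tumor 1 (0.037). The spindle gene Tpx2 rose by 1.69 ± 0.22 (adjusted p = 0.00195), while the mitotic genes Kif20a (-0.89 ± 0.15), Cdc20 (-0.88 ± 0.18) and Plk1 (-0.77 ± 0.17) fell. So did Cenpf (-0.67 ± 0.16) and Aurka (-0.62 ± 0.15), chosen after their values were seen. In the unfolded protein and integrated stress response 1 of 20 members rose, the cystine carrier Slc7a11 (0.76 ± 0.18), and 1 fell, Herpud1. The stress response genes had 1 higher and 2 lower adjusted over the list alone, and 5 higher and 6 lower with the replicate block. Stress response differences had a median of -0.14 (-0.17 among numbers 1 and 2, -0.11 in number 3), with a camera adjusted p = 0.406. Slc7a11 was not called on the mean of its 2 probe sets (adjusted p = 0.754). Immediate early genes, which tissue dissociation can also induce, were higher in 6 of 19 cases and lower in 2. The immediate early genes had 9 higher and 2 lower adjusted over the list alone, and 10 higher and 2 lower with the replicate block. Immediate early differences had a median of 0.31 (0.31 among numbers 1 and 2, 0.33 in number 3), with a camera adjusted p = 0.00194, or adjusted p = 0.825 with an estimated correlation. The immediate early call was lost by fry (adjusted p = 0.127). The heat-shock gene Hspa1b (2.53 ± 0.27, adjusted p = 5.6e-04), Fos (1.24 ± 0.23) and Dusp1 (1.21 ± 0.14) rose, and Btg2 (-0.88 ± 0.14) and Jund (-0.87 ± 0.23) fell. Jund was not called with no filter on dim probe sets (adjusted p = 0.0537), on the mean of its 2 probe sets (0.354) or among numbers 1 and 2 (0.0615). Cdc20 was not called among numbers 1 and 2 (adjusted p = 0.0712). Matrix remodelling and angiogenesis genes had 3 higher and 4 lower of 21. The matrix genes had 3 higher and 6 lower adjusted over the list alone, and 5 higher and 7 lower with the replicate block. Matrix differences had a median of -0.20 (-0.24 among numbers 1 and 2, -0.22 in number 3), with a camera adjusted p = 0.504. Thrombospondin 1, Thbs1 (1.37 ± 0.16, adjusted p = 8.2e-04), Vegfa and the membrane protease Mmp14 (0.85 ± 0.16) rose, and the gelatinase Mmp9 (-1.12 ± 0.17), Pdgfb (-0.81 ± 0.15), Fn1 and Mmp8 fell. Cdc20 without spleen 1/2 or tumor 1 (adjusted p up to 0.082), Plk1 without spleen 1/2 or tumor 1/2 (adjusted p up to 0.104) and Slc7a11 without spleen 1/2 or tumor 1/2/3 (adjusted p up to 0.146) lost the call. Fos without spleen 2 (adjusted p = 0.0506), Jund without spleen 1/2/3 or tumor 1/2 (adjusted p up to 0.139) and Mmp14 without spleen 1/2 (adjusted p up to 0.0676) lost the call. Pdgfb without spleen 2 or tumor 1 (adjusted p up to 0.0679) and Fn1 without spleen 2 or tumor 1/2 (adjusted p up to 0.084) lost the call.

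Markers of other cells that a sort from these tissues could hold gave 1 list call by camera and another by fry. These tests set tumor against spleen, so other cells present alike in both groups would give no call. By camera non-classical monocyte genes were the only one of 16 marker lists called at an adjusted p under 0.05, and by fry the platelet list was the only one; the non-classical list had 4 of 10 lower. The non-classical genes had 0 higher and 5 lower adjusted over the list alone, and 1 higher and 7 lower with the replicate block. Non-classical differences had a median of -0.48 (-0.46 among numbers 1 and 2, -0.55 in number 3), with a camera adjusted p = 0.0219, or adjusted p = 0.825 with an estimated correlation. The non-classical call was lost with a 50th percentile filter (adjusted p = 0.0704), among numbers 1 and 2 alone (0.137), with number 3 as a batch term (0.0552) and by fry (0.118). Spn, or CD43 (-1.18 ± 0.20, adjusted p = 0.00652), Pou2f2 (-1.03 ± 0.18) and Fabp4 fell, as did Eno3 (-0.95 ± 0.16), chosen after its value was seen. Cd36 stood at -0.55 ± 0.19 (adjusted p = 0.129, and adjusted p = 0.00618 with the block). NK and cytotoxic genes had 1 of 10 higher, Klrk1, or NKG2D (1.73 ± 0.23, adjusted p = 0.00209). Klrd1 stood at 0.76 ± 0.21 (adjusted p = 0.0589, and 6.7e-04 with the block). The NK cell genes had 2 higher and 0 lower adjusted over the list alone, and 2 higher and 0 lower with the replicate block. NK cell differences had a median of 0.23 (0.15 among numbers 1 and 2, 0.44 in number 3), with a camera adjusted p = 0.0538. The NK cell list was called with the replicate block (adjusted p = 0.0309), with number 3 as a batch term (0.0421), with quantile normalization and the block (0.0282), without spleen 1 (0.0142), without spleen 2 (0.0139) and without tumor 3 (0.00797). T cell markers had 1 higher, Il7r (0.57 ± 0.15, adjusted p = 0.0451, and 0.0501 with no pseudocount), and 1 lower, Cd3g (-1.36 ± 0.18, adjusted p = 0.00219), of 12. Cd28 stood at -0.80 ± 0.22 (adjusted p = 0.0506, and 0.0046 with the block). The T cell genes had 1 higher and 2 lower adjusted over the list alone, and 1 higher and 3 lower with the replicate block. T cell differences had a median of -0.21 (-0.19 among numbers 1 and 2, -0.23 in number 3), with a camera adjusted p = 0.244. The T cell list was called without spleen 3 (adjusted p = 0.0262). B cell markers had 2 of 12 lower, Spib (-1.01 ± 0.17) and Cd22 (-0.70 ± 0.17), with Ighm at -0.32 ± 0.31 (adjusted p = 0.714). The 7 probe sets of Ighm stood between -2.39 and 0.15. The B cell counts were the same adjusted over the list alone. B cell differences had a median of -0.23 (-0.14 among numbers 1 and 2, -0.36 in number 3), with a camera adjusted p = 0.244. Neutrophil markers had 2 of 14 lower, Mmp9 and Mmp8 (-0.68 ± 0.16). Mcemp1 stood at 0.05 ± 0.15 (adjusted p = 0.949). The neutrophil genes had 0 higher and 3 lower adjusted over the list alone, and 1 higher and 4 lower with the replicate block. Neutrophil differences had a median of -0.09 (-0.11 among numbers 1 and 2, -0.15 in number 3), with a camera adjusted p = 0.329. Platelet markers had 1 of 9 lower, Ppbp, a platelet chemokine (from 9.13 ± 0.31 to 7.13 ± 0.23, adjusted p = 4.4e-04). Itgb3 stood at -0.50 ± 0.18 (adjusted p = 0.139, and 0.0121 with the block). The platelet counts were the same adjusted over the list alone, and 0 higher and 2 lower with the replicate block. Platelet differences had a median of -0.15 (-0.16 among numbers 1 and 2, -0.24 in number 3), with a camera adjusted p = 0.243. The platelet list was called by fry (adjusted p = 0.0446). Cd22 without spleen 1/2/3 or tumor 1/2 (adjusted p up to 0.146), Il7r without spleen 1/2 or tumor 1/2/3 (adjusted p up to 0.193) and Mmp8 without spleen 1/2/3 or tumor 1/2 (adjusted p up to 0.141) lost the call. Fabp4 without spleen 1/2/3 or tumor 1/2 (adjusted p up to 0.103) lost the call.

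Conventional dendritic cell markers had 3 higher and 1 lower of 10. The higher ones were Zbtb46 (0.89 ± 0.17, adjusted p = 0.012), Dpp4 (0.87 ± 0.20) and Ccr7, and the lower one Itgax. The conventional dendritic genes had 4 higher and 1 lower adjusted over the list alone, and 4 higher and 2 lower with the replicate block. Conventional dendritic differences had a median of 0.07 (0.05 among numbers 1 and 2, 0.10 in number 3), with a camera adjusted p = 0.329. Ccr7 had a level of 11.56 ± 0.09 and the actin bundler Fscn1 one of 10.96 ± 0.06 on the spleen arrays. Fscn1 stood at 0.45 ± 0.13 (adjusted p = 0.0758, and 0.00838 with the block). Plasmacytoid dendritic cell markers had 1 of 7 higher, the transcription factor Tcf4 (1.92 ± 0.23, adjusted p = 0.00115). Lag3 stood at 0.73 ± 0.20 (adjusted p = 0.0571, and 0.00181 with the block) and Pacsin1 at -0.19 ± 0.21 (adjusted p = 0.744). The plasmacytoid genes had 2 higher and 0 lower adjusted over the list alone, and 2 higher and 0 lower with the replicate block. Plasmacytoid differences had a median of 0.10 (0.04 among numbers 1 and 2, 0.24 in number 3), with a camera adjusted p = 0.0915. Red pulp macrophage markers, which belong to the spleen, had 1 higher, Vcam1, and 1 lower, Slc40a1, of 8. Hmox1 stood at -0.27 ± 0.17 (adjusted p = 0.47). The red pulp counts were the same adjusted over the list alone, and 1 higher and 3 lower with the replicate block. Red pulp differences had a median of -0.13 (-0.12 among numbers 1 and 2, -0.15 in number 3), with a camera adjusted p = 0.889. Endothelial markers had 2 higher, the VEGF receptors Kdr (2.88 ± 0.23, adjusted p = 1.1e-04) and Flt1, and 1 lower, Vwf (-1.37 ± 0.15), of 12. Eng stood at 0.59 ± 0.17 (adjusted p = 0.0624, and 0.00263 with the block). The endothelial genes had 3 higher and 1 lower adjusted over the list alone. Endothelial differences had a median of -0.02 (-0.04 among numbers 1 and 2, 0.06 in number 3) and a mean of 0.30, with a camera adjusted p = 0.329 directed up. Fibroblast markers had 1 higher, Fap, which was dim in spleen (1.30 ± 0.32), and 1 lower, Col6a1 (-0.56 ± 0.15), of 11. Acta2 stood at -0.54 ± 0.16 and Col1a1 at -0.47 ± 0.19 (adjusted p = 0.0798 and 0.179, and 0.00342 and 0.00649 with the block). The fibroblast genes had 1 higher and 2 lower adjusted over the list alone, and 2 higher and 3 lower with the replicate block. Fibroblast differences had a median of -0.10 (-0.23 among numbers 1 and 2, -0.02 in number 3), with a camera adjusted p = 0.771. Col6a1 was not called after quantile normalization (adjusted p = 0.127), median centring (0.0505) or cyclic loess (0.175), with the trended and robust prior (0.0629), or on the mean of its 2 probe sets (0.273). Epithelial markers had 1 of 8 lower, Krt19 (-0.92 ± 0.23, adjusted p = 0.102 among numbers 1 and 2). Epcam stood at 0.45 ± 0.24, Krt8 at 0.06 ± 0.25 and Cdh1 at -0.38 ± 0.23 (adjusted p = 0.0159 with the block). The other probe set of Cdh1 stood at -0.06. The epithelial counts were the same adjusted over the list alone, and 0 higher and 2 lower with the replicate block. Epithelial differences had a median of -0.02 (-0.01 among numbers 1 and 2, -0.08 in number 3), with a camera adjusted p = 0.912. Zbtb46 without spleen 1/2 or tumor 2 (adjusted p up to 0.0627), Dpp4 without spleen 1/2 or tumor 1/3 (adjusted p up to 0.12) and Ccr7 without any one array (adjusted p up to 0.158) lost the call. Itgax without tumor 1 (adjusted p = 0.0594), Fap without spleen 1/2/3 or tumor 1 (adjusted p up to 0.123) and Col6a1 without spleen 1/2 or tumor 1/2/3 (adjusted p up to 0.208) lost the call. Krt19 without spleen 1/3 or tumor 1/2 (adjusted p up to 0.163) lost the call.

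Of the remaining marker lists none had a called member by limma. Among 11 melanocytic markers, Mitf stood at 0.26 ± 0.22, Sox10 at 0.15 ± 0.26 and S100b at -0.28 ± 0.14. The melanocytic counts were the same adjusted over the list alone. Melanocytic differences had a median of 0.03 (0.04 among numbers 1 and 2, -0.04 in number 3), with a camera adjusted p = 0.819. Among 10 myeloid progenitor markers, Prtn3 stood at 0.58 ± 0.47, Flt3 at 0.09 ± 0.17 and Kit at -0.55 ± 0.31 (adjusted p = 0.00432 with the block). The progenitor counts were the same adjusted over the list alone, and 0 higher and 2 lower with the replicate block. Progenitor differences had a median of 0.04 (0.05 among numbers 1 and 2, -0.17 in number 3) and a mean of -0.04, with a camera adjusted p = 0.912 directed down. Among 9 mast cell, basophil and eosinophil markers, Cpa3 had levels of 9.91 ± 0.36 in spleen and 9.86 ± 0.28 in tumor, and Epx stood at 0.32 ± 0.19 and Siglecf at -0.65 ± 0.19 (adjusted p = 0.0744, and 0.0014 with the block). The mast cell counts were the same adjusted over the list alone, and 0 higher and 1 lower with the replicate block. Mast cell differences had a median of -0.06 (-0.01 among numbers 1 and 2, -0.26 in number 3), with a camera adjusted p = 0.819. Among 4 erythroid markers, Klf1 stood at 0.20 ± 0.21, Ermap at -0.12 ± 0.15 and Slc4a1 at -0.04 ± 0.25. The erythroid counts were the same adjusted over the list alone. Erythroid differences had a median of -0.04 (0.01 among numbers 1 and 2, 0.00 in number 3) and a mean of 0.00, with a camera adjusted p = 0.912 directed up, while fry pointed down. At an unadjusted p under 0.05, 1 of the 34 members of these 4 lists passed.

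**Figure D4:**
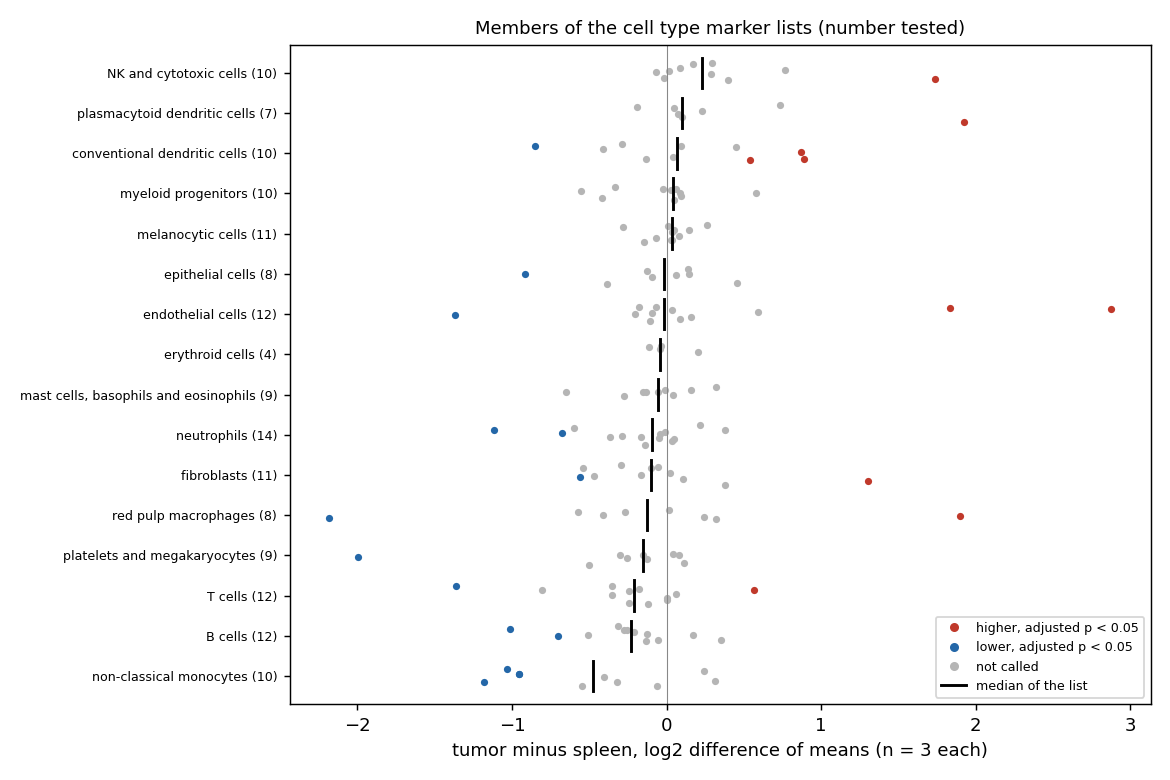
Each dot is a tested member of a cell type marker list, placed by its log2 difference tumor minus spleen (n = 3 each), and the bar is the list's median. Medians lay between -0.48 and 0.23, and single genes such as Kdr, Tcf4, Vcam1, Ppbp and Slc40a1 stood apart from their lists.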

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

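The tests of an array-wide offset, of fewer T and NK cells, of another strain or day, of dendritic cells left in the sort, of other cells than the labels name, of plasmacytoid dendritic cells and of Ifna probe sets reading each other were chosen after the results were seen, and the test of other cell types in the samples numbered 3 and the counts over other splits were fixed before.

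Signal outside the genes tested also differed between the groups. Of 10575 probe sets that are not listed with a gene and passed the same filter, 69 were called by limma, 54 higher and 15 lower in tumor, and 58 with the replicate block. Of 1462 probe sets that name several genes, 140 were called, 70 higher and 70 lower, and 327 with the replicate block.

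The arrays numbered 3 deviated from numbers 1 and 2 in the same genes in both groups. Their array medians of log2 intensity were higher, at 4.73 and 4.76 against 4.50 to 4.51 on the others. Such an array-wide offset alone is argued against, since the deviations of spleen 3 and tumor 3 still correlated at 0.70 across genes after quantile normalization. Whether number 3 was normalized in a separate batch was not tested and stays open. More of another cell type stays open: the highest marker list median, the smaller of both arrays, was 0.131 ± 0.282 (SD over plasmacytoid dendritic cell markers), under the bound of 0.3 set beforehand, but that bound left out that members of a list can go both ways, as in the mast cell list (0.0932 ± 0.499) and with the B cell gene Cd79a at 1.39 and 1.01. Fewer T and NK cells in number 3 may account for part of the pattern and stay open, with T cell marker medians of -0.46 in spleen and -0.54 in tumor and NK cell medians of -0.60 and -0.394, and Cd3e at -1.34 and -1.43. Animals of another strain, or another day, may lie behind number 3: 65 genes deviated by over 1 (log2) alike in both arrays and 1 in opposite directions, led by Olfr1454 (-5.89 and -5.18) and Myl12a (3.01 and 2.23), but a strain and a day cannot be told apart without a label, and the design names no biological difference between the numbers.

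Itgax and other genes of dendritic cells gave signal on arrays whose cells were sorted as CD11c-negative, at the 98.9 percentile of the tested genes in spleen and 96.5 in tumor for Itgax, a rank among probe sets that are not on 1 scale. In spleen the other genes behind the sort had ranks of 97.5 (Adgre1), 96.3 (Itgam), 64.4 (Ccr2), 63.8 (Ly6c2) and 4.51 (Ly6c1). Conventional dendritic cells left in the sort could add signal of Itgax and other dendritic cell genes. Of their markers 50 percent lay above the 75th percentile in spleen, the list holding Ccr7 (11.56), Itgax (11.16), Fscn1 (10.96), Xcr1 (4.59) and Itgae (5.44). A gate against CD11c is meant to remove such cells. Flow cytometry sorts on CD11c protein at the cell surface, while the arrays read Itgax RNA, and no protein was measured here. The Itgax signal therefore does not show whether the gate worked. How well the gate removed such cells was not tested, so the gate decides nothing here. A list of genes high in GM-CSF cultures of bone marrow and one of Ly6C-high monocytes, with 53.8 and 12.5 percent above the 95th percentile in spleen, decide nothing on other cells than the labels name, since they were written after levels of some members had been seen. Both explanations stay open, because levels of different probe sets are not on 1 scale, which leaves these tests without weight, and no array of known cells was at hand for comparison. A monocyte state particular to these mice stays open as well, untested.

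Transcripts of type I interferons themselves were higher on the tumor arrays, with 8 of 9 tested Ifna genes called higher (median 2.12), Ifnb1, dim in spleen as were Ifna2, Ifna9 and Ifna11, at 4.41, Ifng at 0.08 (adjusted p = 0.924) and Ifna7 at -0.15 (adjusted p = 0.922). Below the filter, and so outside this count and median, were Ifna12 (0.10), Ifna13 (0.29) and Ifna16 (-0.18). Ifna11 and Ifnb1, at 2.88 and 3.29 in spleen, passed the filter through their tumor values alone, so the filter favours dim genes that rise. Plasmacytoid dendritic cells, which make these transcripts, could be more frequent in the tumor sort, but their markers had a median change of 0.10 with Tcf4 alone called (1.92, a gene other cells express too), which leaves the question open for a small share of cells. Ifna probe sets that read each other's transcripts may inflate the count of genes, while their changes ranged over 4.92 (log2), so they did not move as 1 gene, and sharing among some of them stays open. The difference between tumor and spleen as tissues is part of the design and remains untested as a cause.

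Chance was examined by splitting the 6 arrays into other groups of 3. Each of the 3 counts had 1 of 10 splits as large, the real one, and 10 splits are too few for a share under 0.05. The real split gave 1952 called genes against at most 0 in any other split, 984 against 0 at 2-fold or more, and 12 shifted lists against at most 11. Every other split has tumor and spleen arrays on both sides. Any difference between tumor and spleen then adds to the spread within each side and lowers the count of called genes. The low gene counts of the other splits therefore do not show what chance alone would give. The list counts of the other splits, from 1 to 11, do not show it either. In each of them the sides hold unequal numbers of tumor arrays, so part of the difference stays and camera can still call lists. Of the 10 splits, 4 part all 3 same-numbered pairs as the real one does, and the others of these gave 0 genes and up to 11 lists.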

How the results depend on the processing

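None of the 112 called named genes and 12 called lists turned direction under any setting, many of which (the block and the priors among them) leave the difference as it is or, as median centring, move all differences alike, while 7 of 32 named genes and the medians of 15 of 26 lists that were not called changed sign under at least 1, 2 and 7 of them under a scaling. Of the 144 named genes 112 were called, of which 62 kept the call throughout, and 20 of the 32 others were called under at least 1 setting, 15 with the replicate block and 10 under a scaling. Leaving out both arrays numbered 3, number 3 as a batch term, no pseudocount, and quantile normalization with the block were chosen after seeing the data. Against 1952 called genes, 1057 higher and 895 lower, the counts were 3506 (1585 and 1921) after quantile normalization, 3289 (1483 and 1806) after median centring, 3184 (1854 and 1330) after cyclic loess, 7102 (2867 and 4235) with array weights, 2936 (1387 and 1549) without both arrays numbered 3, 5466 (2181 and 3285) with the batch term, and 901 (520 and 381) without moderation. With the replicate block, which takes equal numbers as pairs, they were 5346 (2153 and 3193), and 5403 (2156 and 3247) with quantile normalization added. For numbers 1 and 2 that pairing is an assumption. The array weights were 1.58, 8.32 and 0.162 for spleen 1 to 3 and 3.36, 0.773 and 0.181 for tumor 1 to 3. Results with array weights therefore lean mostly on spleen 2 and tumor 1. The block ended no call of a named gene or list, and changed no other call of a named gene or list than those given in the report. It also raised counts of list members by up to 1.5 times where none is given there. All 1952 called genes were also called with the block. The other counts of called genes, with no filter, a 50th percentile filter, the mean of probe sets, the trended and robust prior or no pseudocount, lay between 1855 and 2145. An adjusted p under 0.01 left 961 genes. Against 984 called genes at 2-fold or more, the count was 557 (416 higher, 141 lower) without moderation, and treat against a minimum of 1.5-fold, run on all genes tested, called 507. With 1 array left out the counts ranged over 1011 to 1924 called, 662 to 1240 higher, 293 to 1036 lower, 843 to 1048 at 2-fold or more, 604 to 837 of them higher and 204 to 424 lower, and 13 to 14 lists shifted against 12; 38 of the 112 named calls were lost in at least 1 such run, 28 without spleen 1, 34 without spleen 2, 7 without spleen 3, 32 without tumor 1, 18 without tumor 2 and 9 without tumor 3. These runs have fewer arrays, and the unmoderated test, which lost 44 named calls, has few degrees of freedom. With an estimated correlation 0 lists passed camera (5 at an unadjusted p under 0.05), fry called 8, the platelet list among them, and the other settings called between 9 and 14. For the other changes the cause was not tested. Changes of dim genes are limited by the signal over background, as 3722 of 22180 genes fell below the filter.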

Other observations

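Grouping genes by symbol, and the test of these families, were chosen after the results were seen. Among 531 families with at least 5 tested genes, 20 held more called rises than the rest of the genes (one-sided Fisher's exact test, adjusted p under 0.05), and 0 held more falls (23 at an unadjusted p under 0.05). The guanylate-binding proteins, GTPases of defence inside cells, were higher in 9 of 9 genes (adjusted p = 3.4e-09), led by Gbp4 (4.98 ± 0.18) and Gbp5 (4.68 ± 0.23). Schlafen genes, regulators of growth and antiviral defence, were higher in 7 of 8 (adjusted p = 2.0e-06), with Slfn4 at 5.09 ± 0.22 and Slfn1 at 3.67 ± 0.25. Membrane proteins of the Ms4a family rose in 6 of 8 (adjusted p = 7.8e-05), with Ms4a6b at 3.84 ± 0.25 and Ms4a6c at 2.62 ± 0.14 beside Ms4a4c. Of the Trim genes, many of which encode ubiquitin ligases, 13 of 59 rose (adjusted p = 0.00158) and 3 fell (12 with the replicate block), among the rises Trim30b (4.05 ± 0.30, dim in spleen), Trim30d (3.73 ± 0.33) and Trim21 (3.13 ± 0.21), and the falls were those of Trim16 (-1.15 ± 0.25), Trim37 (-0.69 ± 0.18) and Trim27 (-0.67 ± 0.13). Over the called members of all 20 families, 0 of 128 turned direction after quantile normalization or cyclic loess. These members were selected as called in the same data, so a turn was unlikely from the start and the count adds little.

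Further families held called rises. Signalling lymphocyte activation genes were higher in 4 of 5 (adjusted p = 0.00271): Slamf6 (1.32 ± 0.19), Slamf8 (1.04 ± 0.16), Slamf9 (0.77 ± 0.18) and Slamf7 (0.67 ± 0.16). Ligands of the TNF family rose in 5 of 8 (adjusted p = 0.00174), with Tnfsf15 (3.20 ± 0.16), Tnfsf9 (2.30 ± 0.16) and Tnfsf8 (2.20 ± 0.35) beside Tnfsf10 and Tnfsf4. Poly-ADP-ribose polymerase genes rose in 5 of 11 (adjusted p = 0.00933), namely Parp14 (from 8.81 ± 0.29 to 11.80 ± 0.20), Parp12 (2.64 ± 0.17), Parp11 (2.23 ± 0.20), Parp9 (1.97 ± 0.17) and Parp8 (1.20 ± 0.23), while Parp1, a gene of DNA repair, fell by 0.80 ± 0.15. The Phf11 group stood out within its family, with Phf11a at 4.44 ± 0.15 and Phf11d at 4.32 ± 0.21, and so did the apolipoprotein L gene Apol9b at 4.21 ± 0.18. Serine protease inhibitors of the Serpinb family rose in 5 of 12 (adjusted p = 0.0131): Serpinb9b (2.60 ± 0.16), Serpinb9 (1.82 ± 0.22), an inhibitor of granzyme B, Serpinb1b (1.20 ± 0.16, dim in spleen), Serpinb1a (0.98 ± 0.25) and Serpinb6b (0.91 ± 0.14). Members of a family share sequence, so their probe sets are not independent counts.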
